A study of Homo sapiens with 18 samples.

How the data were processed

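Gene expression was measured in CAS-1 cells, an established human glioblastoma line, on Affymetrix arrays hybridised with labelled cDNA made from total RNA. The 18 arrays fall into 3 groups of 6, taken from the labels: a single-cell clone transduced with a CRISPR vector against IL4I1 (IL4I1-KO), the mixed population transduced with a non-targeting control vector (NTC), and a single-cell clone of that control population (NTC.01). Cells grew for 24 h after seeding and then for 72 h in medium without serum, per the labels' protocols. The series' design text calls the 6 replicates independent experiments. It names 1 knockout clone made with 1 guide, so a difference between IL4I1-KO and a control can belong to the clone as well as to the knockout.

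The deposited table holds log2 values, 1 column per array, made by the authors with the R package oligo and robust multi-array average (RMA), per the submitters' processing notes, which give no versions. The array design, the genome build and the rule by which probe sets entered the table are not given in the sources used here. The table has 14530 probe sets with values from 1.02 to 13.99, and every probe set had at least 4 arrays at 7.73 or higher, so that transcripts dim on nearly all arrays are not analysed here. No measure of background was used here, so a fold against a group with low values is a difference of listed values, and its true size is not known. Array medians lay between 8.73 and 8.79. Arrays give no counting depth, and the number of arrays limits the precision.

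Probe sets were named through the platform annotation supplied for this series. Of the 14530, 12699 had 1 gene symbol, 716 had several and 1115 had none. Symbols were updated through the RefSeq gene table of assembly GRCh38.p14, which changed 940 of them through a unique synonym and left 37 that are not current symbols. That table was used for names, for the order of genes by start position and for the chromosome of each gene. No coordinates are given here. Each gene was represented by its probe set with the highest mean over the 18 arrays, which gave 12655 genes. Probe sets with several symbols or none were left out of the gene tests.

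The 3 comparisons (IL4I1-KO against NTC.01, IL4I1-KO against NTC, NTC.01 against NTC) were contrasts of 1 model fitted to all 18 arrays with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, so that they share 1 estimate of the spread. Tests were two-sided and adjusted by Benjamini-Hochberg over the 12655 genes, with a threshold of 0.05. A gene changed the same way against both controls when both IL4I1-KO contrasts passed the threshold with 1 sign. Because these 2 contrasts share the 6 IL4I1-KO arrays, their overlap was compared with 100 simulations without effect, made by reassigning the residuals of the 18 arrays, and with the IL4I1-KO arrays split between the controls. Single values were compared by two-sided exact permutation tests over the 924 splits of 6 against 6 arrays, whose smallest p is 0.00216.

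Before the data were examined, 23 gene lists were fixed. They cover targets of the aryl hydrocarbon receptor (AHR), tryptophan, phenylalanine and tyrosine catabolism, amino acid transporters, the ATF4 integrated stress response, the NRF2 oxidative stress response, the interferon response, inflammatory cytokines and NF-kB targets, antigen presentation, hypoxia and glycolysis, cholesterol synthesis, the cell cycle, p53 targets, extracellular matrix and mesenchymal genes, TGF-beta and YAP targets, immediate early and ERK feedback genes, Wnt and Notch targets, markers of astrocytes, of the oligodendrocyte lineage, of neurons and neural progenitors, of macrophages, microglia and lymphocytes, and of endothelium, pericytes and epithelium, the heat shock and unfolded protein response, and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists of a contrast, with an estimated correlation and fry as alternatives; fry asks whether a list's members move on balance 1 way and does not compare them with other genes. A list's score on an array is the mean over its members of the log2 value minus that gene's mean over the 18 arrays; scores were compared by exact permutation tests, which do not compare a list with other genes either. The score tests, and fry for lists other than the AHR list, were not among the tests fixed in advance.

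The genes named were also chosen by a rule fixed in advance. It takes NUP62 and AHR with its partner and best-known targets; for each comparison the 10 largest rises and 10 largest falls past the threshold whose 6 values do not overlap the other group's; the 10 rises and 10 falls largest against both controls with IL4I1-KO outside the range of all 12 control arrays; and up to 4 members of each list past the threshold, or 2 members as values where none passed. Only genes with a probe set of their own can be named. CYP1A1 has none here, and IL4I1 shares its probe set with NUP62.

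The replicate numbers are shared by the 3 groups. Whether they pair the arrays was checked before any call was seen, on all probe sets, from the correlation of same-numbered arrays' deviations from their group means. All 6 correlations were over 0.1 for IL4I1-KO with NTC.01 (0.123 to 0.675) and for NTC.01 with NTC (0.177 to 0.690), which counts as paired, but not for IL4I1-KO with NTC (0.0270 to 0.652). The pairing comes from this check alone; the labels do not say that a number marks a shared day. As the numbers are shared by all 3 groups, the limit of 0.1 does not show that only 2 of the comparisons are paired. Over the 12655 genes, computed later, the lowest correlation of IL4I1-KO with NTC.01 was 0.0958, just under the limit, so this pairing is borderline. For these 2 paired comparisons the fit with the replicate number as a block is given beside a result where it changes the call of a list or moves a count by over 1.5 times; for IL4I1-KO against NTC and for the genes shared by both knockout comparisons it stands with the other alternatives.

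The alternatives fixed in advance were a fit to 2 groups at a time, trend and robust moderation, array weights, quantile normalization, median centring, a filter leaving out the dimmest 40% of genes, the mean of a gene's probe sets, the replicate number as a fixed or random block, stricter thresholds, all probe sets, and each array left out in turn. Leaving out all 3 arrays of replicate 6, the small nucleolar RNA genes or the X-linked genes, and for lists median centring, each array left out and, beyond the AHR list, fry, as well as list scores without the member of the largest change, were chosen after seeing the data. The fit was tested on simulated data with the real genes' means and spread and 200 changed genes among the 12655. For IL4I1-KO against NTC it recovered 50% of genes changed by 0.5, 92% of those changed by 1 and 100% of those changed by 2 on the log2 scale; for IL4I1-KO against NTC.01 the shares were 62%, 91% and 100%. Figures were drawn with matplotlib 3.10.9.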

Results

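Gene expression was profiled in CAS-1 glioblastoma cells that carry a CRISPR knockout of IL4I1 and in 2 control lines of the same cells. IL4I1 is a secreted amino acid oxidase that degrades phenylalanine, tyrosine and tryptophan, and products it makes from tryptophan can activate AHR, a ligand-dependent transcription factor. The comparisons ask which genes differ between the knockout clone and cells that received a non-targeting guide, either as a mixed population (NTC) or as a clone (NTC.01). Each group had 6 arrays. Values are RMA-normalised log2 intensities, where a difference of 1 is 2-fold, and differences are given as log2 fold changes ± SE from limma (n = 6 per group). Within their group, arrays of replicates 1 to 5 had mean correlations across genes of 0.914 to 0.951, and the 3 arrays of replicate 6 had 0.861 to 0.905.

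The probe set annotated to IL4I1 was lower in the knockout clone than in either control. It averaged 7.97 ± 0.126 (SD, n = 6) in IL4I1-KO, 9.0 ± 0.299 in NTC.01 and 8.90 ± 0.214 in NTC, and the highest IL4I1-KO array (8.11) lay below the lowest array of NTC.01 (8.62) and of NTC (8.69). The differences were −1.03 against NTC.01 and −0.94 against NTC, each with an exact permutation p of 0.00216, the smallest that 6 against 6 arrays can give. NTC.01 and NTC differed by 0.10 (exact permutation p = 0.528). This probe set is also annotated to NUP62, a nuclear pore protein gene that overlaps IL4I1, so it does not measure IL4I1 alone. The probe set of NUP62 itself was lower too (−0.61 ± 0.11 against NTC.01 and −0.57 ± 0.11 against NTC), with 0.04 ± 0.11 between the controls. The direction given by the labels holds for the shared probe set, and the part that belongs to IL4I1 cannot be read from it.

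**Figure D1:**
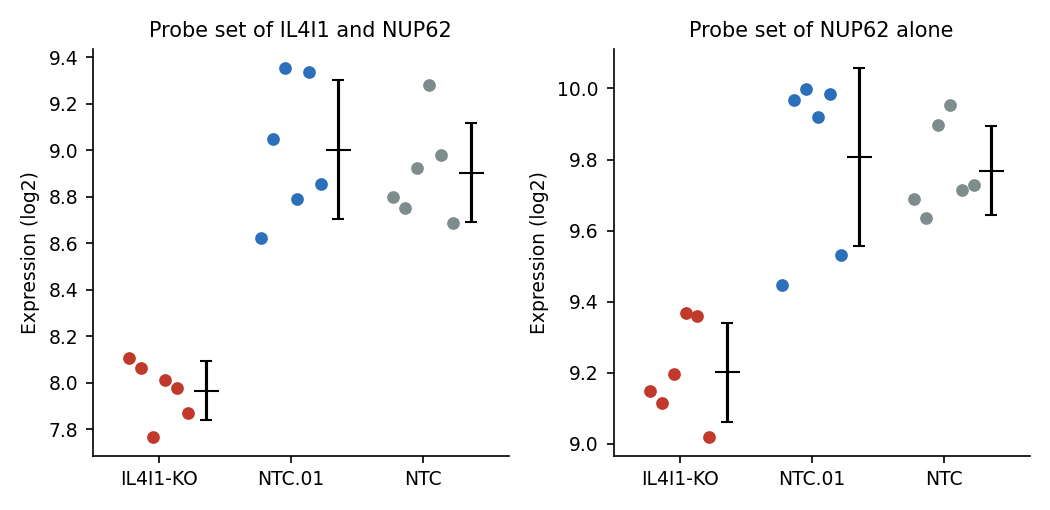
Expression (log2) on each of the 18 arrays for the probe set annotated to IL4I1 and NUP62 (left) and for the probe set of NUP62 alone (right), with each group's mean and SD (n = 6) as a bar beside its points. In the left panel all 6 IL4I1-KO arrays lie at 8.11 or lower and all 12 control arrays at 8.62 or higher; the vertical axes do not start at 0.

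Compared with the control clone NTC.01, the knockout clone had more transcripts of the chemokine gene CCL11 (4.32 ± 0.41), the protocadherin gene PCDHB5 (3.44 ± 0.16), SCRG1 (3.34 ± 0.26), CSMD1 (3.27 ± 0.19) and the cancer-testis gene MAGEC1 (3.12 ± 0.13). MAB21L2, the smooth muscle actin gene ACTG2, CSAG1, MKX and the guanylate cyclase gene GUCY1A1 followed, with log2 fold changes from 2.31 down to 1.89. The largest fall was that of SFRP2, a secreted modulator of Wnt signalling (−4.29 ± 0.18). LRRN1 (−3.20 ± 0.18), the calcium sensor gene VSNL1 (−2.98 ± 0.15), the axon guidance receptor gene ROBO2 (−2.84 ± 0.30) and the peptide receptor gene VIPR1 (−2.83 ± 0.24) came next. HEPH, DGKB, TMEFF2, PADI2 and the collagen-binding integrin gene ITGA2 fell as well, with values from −2.71 to −2.51. In 18 of these 20 genes the dimmer group averaged under 7.73, a level that each probe set of the table reaches on at least 4 arrays, so the sizes of these folds depend on a background that was not measured here. In all, 1600 of 12655 genes passed the threshold, 924 higher and 676 lower in IL4I1-KO. Of these, 65 and 117 changed at least 2-fold. The calls were spread unevenly over the chromosomes. The X chromosome held 115 rises and 17 falls among 397 genes, and chromosome 20 held 98 and 1 among 361. Chromosome 9 held 89 rises and 10 falls among 492 genes, and chromosome 19 held 12 and 109 among 840. In IL4I1-KO against NTC the X held 5 rises and 81 falls, and chromosome 20 held 27 and 18. There chromosome 9 held 32 and 14, and chromosome 19 held 11 and 107. In NTC.01 against NTC the X held 12 and 202, and chromosome 20 held 2 and 42. Chromosome 9 held 10 and 39 between the controls, and chromosome 19 held 12 and 14. Over all 12655 genes, the 6 values of one group lay wholly outside those of the other for 762, where chance gives 0.216% of genes, or 27.4. With the replicate number as a block 3191 genes passed, 1888 higher and 1303 lower, and these included all 1600.

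Among the fixed gene lists, cell cycle genes were lower in IL4I1-KO than in NTC.01. Of 32 measured members 6 fell and none rose (15 fell adjusted over the list alone), with a median of −0.50 (camera, adjusted p = 1.51e-07; adjusted p = 0.705 with an estimated correlation). The 6 falls became 1 without NTC.01 4, 2 without IL4I1-KO 1 or NTC.01 2, 3 without IL4I1-KO 2 or 5, and 10 without NTC.01 1 or 5. TOP2A, the DNA topoisomerase of dividing cells, fell by 0.96 on the log2 scale (SE 0.23). The list's mean score was lower in IL4I1-KO in 6 of 6 same-numbered pairs, and the unpaired exact permutation p was 0.0325 (0.124 after adjustment over the 23 lists). Of 19 genes of the NRF2 oxidative stress response 3 rose and none fell (4 rose adjusted over the list alone; adjusted p = 0.0467, and adjusted p = 0.705 with an estimated correlation). They were led by the quinone reductase gene NQO1 (0.79 ± 0.10) and the aldo-keto reductase gene AKR1C3 (0.77 ± 0.14). In the ATF4 list 3 of 24 rose and none fell (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0360, and adjusted p = 0.733 with an estimated correlation). The lipoprotein receptor gene VLDLR rose most (0.89 ± 0.13). Of 20 immediate early and ERK feedback genes 5 fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 0.0360, and adjusted p = 0.705 with an estimated correlation). The falls included the AP-1 subunit gene FOSL1 (−1.12 ± 0.23) and PHLDA1 (−0.83 ± 0.11). The NRF2, ATF4 and immediate early calls each ended without the 3 arrays of replicate 6 (adjusted p = 0.0530 for each) and with single arrays left out: for ATF4 IL4I1-KO 5 or 6 or NTC.01 3 or 4 (adjusted p up to 0.109), for NRF2 IL4I1-KO 3 or 5, NTC 6 or NTC.01 1, 3, 4 or 6 (up to 0.118), and for immediate early genes IL4I1-KO 2, 5 or 6 or NTC.01 1, 3 or 4 (up to 0.0716). The 3 ATF4 rises became 1 without IL4I1-KO 5 or 6 or NTC.01 3 or 4 and 5 without NTC.01 6, and the 5 immediate early falls became 2 without IL4I1-KO 2 and 3 without IL4I1-KO 6 or NTC.01 4.

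Extracellular matrix and mesenchymal genes moved both ways against NTC.01: 10 of 33 rose and 4 fell (10 and 6 adjusted over the list alone; adjusted p = 0.60). The rises included the proteoglycan gene DCN (1.52 ± 0.21), the collagen gene COL3A1 (1.34 ± 0.23), POSTN (0.96 ± 0.17) and the collagen cross-linking enzyme gene LOX (0.84 ± 0.13). The matrix score was higher in IL4I1-KO in 6 of 6 pairs (exact permutation p = 0.00649, and 0.0498 after adjustment over the 23 lists), and without DCN this score did not pass (exact permutation p = 0.0476, adjusted 0.229). Neuronal and neural progenitor markers had 3 falls and no rise among 14 (3 adjusted over the list alone; adjusted p = 0.0508), among them CD24 (−0.88 ± 0.09) and the transcription factor gene SOX11 (−0.50 ± 0.13). Their score was lower in 6 of 6 pairs, with the smallest exact permutation p of 0.00216 (0.0249 adjusted over the lists), and without CD24 it did not pass either (exact permutation p = 0.0303, adjusted 0.229). Of 18 interferon response genes 4 fell and 1 rose (5 and 3 adjusted over the list alone; adjusted p = 0.229). The falls were those of IFI44L (−1.03 ± 0.21), the transcription factor gene IRF1 (−0.61 ± 0.14) and the guanylate binding protein genes GBP2 (−0.72 ± 0.15) and GBP1 (−0.48 ± 0.12). With the replicate number as a block, 23 cell cycle genes fell and none rose. The same block gave 9 rises and 1 fall for ATF4, 7 and 0 for NRF2, 3 and 7 for immediate early genes, 11 and 7 for the matrix list and 3 and 4 for the interferon list, and no call of a list by camera changed.

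The score and fry ask another question than camera, since neither sets a list against other genes. Against NTC.01 camera called 4 of the 23 lists, and only the NRF2 list among them also passed by score (exact permutation p = 0.00216, adjusted 0.0249) and by fry (adjusted p = 0.00987). With fry the cell cycle, ATF4 and immediate early lists did not pass (adjusted p = 0.145, 0.132 and 0.127), while the neuronal list (adjusted p = 0.000276) and the heat shock list (adjusted p = 0.0250) did. The ATF4 and immediate early scores gave exact permutation p of 0.0498 and 0.145 (0.164 and 0.303 adjusted). In 9 lists all 6 pairs moved 1 way, among them the 4 that camera called, which gives a paired exact permutation p of 0.0313, the smallest that 6 pairs can give (0.0799 adjusted over the lists).

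Against the mixed control NTC, large rises were those of PCDHB5 (3.44 ± 0.16), the chondroitin synthase gene CHSY3 (3.02 ± 0.12) and the sodium-calcium exchanger gene SLC24A3 (2.48 ± 0.12). FIBIN, CCDC85A, TSPAN7, OLFM2, CCL11 and the sialyltransferase gene ST6GAL1 followed, with values from 2.32 to 1.98. SCRG1 rose as well, from 4.89 ± 0.564 (SD, n = 6) in NTC, where it was the lowest of all probe sets on 3 of 6 arrays, to 8.75 ± 0.421. Among the falls was that of the decoy receptor gene IL13RA2 (−3.97 ± 0.32). ITGA2 (−3.80 ± 0.23), PKIB (−3.35 ± 0.22), TMPRSS15 (−3.34 ± 0.20), LYPD1 (−3.18 ± 0.19), the urea transporter gene SLC14A1 (−3.11 ± 0.29), CDH6, ANGPT2 and SFRP2 came next, the last 3 between −2.95 and −2.82. The heparan sulfate enzyme gene NDST4 fell from 8.30 ± 0.273 (SD, n = 6) in NTC to 3.49 ± 0.523, the lowest of all probe sets on 5 of 6 IL4I1-KO arrays. No exact fold is given for SCRG1 and NDST4 at these levels, ST6GAL1 was the lowest probe set on 1 NTC array, and in all 20 genes the dimmer group averaged under 7.73. The comparison called 1486 of 12655 genes, 552 higher and 934 lower in IL4I1-KO, with 71 and 151 of them changed at least 2-fold. Of the 1486, 370 also passed with the same sign in NTC.01 against NTC, a comparison that shares the NTC arrays. Over all genes, groups did not overlap for 960, where chance gives 27.4.

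Genes of the ATF4 integrated stress response, among them enzymes of amino acid synthesis, were higher in IL4I1-KO than in NTC. Of 24 measured members 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.69 (camera, adjusted p = 1.06e-11; adjusted p = 0.0913 with an estimated correlation). They included VLDLR (1.37 ± 0.13), the asparagine synthetase gene ASNS (1.18 ± 0.18) and the glutathione-degrading enzyme gene CHAC1 (1.04 ± 0.17). Amino acid transporters shared this direction, with 6 of 15 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.00382, and adjusted p = 0.0913 with an estimated correlation). The cystine carrier gene SLC7A11 (1.16 ± 0.17), the large neutral amino acid carrier gene SLC7A5 (0.88 ± 0.16) and the glutamine carrier gene SLC1A5 (0.88 ± 0.13) rose, while SLC7A8 (−1.70 ± 0.29) and the glutamate carrier gene SLC1A3 (−0.67 ± 0.14) fell. Against NTC.01 the transporter list had 2 falls and no rise (camera, adjusted p = 0.950). NRF2 genes had 5 rises and no fall among 19 (5 and 1 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.275 with an estimated correlation), with AKR1C3 (1.21 ± 0.14), NQO1 (1.01 ± 0.10) and the thioredoxin reductase gene TXNRD1 (0.49 ± 0.11).

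Cell cycle genes were again lower, with 12 of 32 fallen and none risen (24 fell adjusted over the list alone), a median of −0.53, and a camera adjusted p of 9.09e-09 (adjusted p = 0.332 with an estimated correlation). The 12 falls became 5 without IL4I1-KO 1 or NTC 3, 6 without NTC 4 and 7 without NTC 2 or 6. TOP2A (−0.97 ± 0.23) and the spindle checkpoint kinase gene BUB1B (−0.92 ± 0.20) were among them, and the list score had an exact permutation p of 0.0152 (0.0317 after adjustment over the lists). Immediate early and ERK feedback genes had 8 falls and 2 rises among 20 (12 and 2 adjusted over the list alone; adjusted p = 4.42e-05, and adjusted p = 0.190 with an estimated correlation), including FOSL1 (−1.53 ± 0.23) and the ERK phosphatase genes DUSP5 (−1.35 ± 0.28) and DUSP4 (−1.34 ± 0.20). Inflammatory cytokines and NF-kB targets had 7 falls and 1 rise among 15 (9 and 2 adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.0913 with an estimated correlation). The 7 falls became 4 without NTC 3 or 4. The monocyte chemoattractant gene CCL2 fell most (−2.31 ± 0.33), and the NF-kB inhibitor genes NFKBIA (−0.82 ± 0.13) and TNFAIP3 (−0.74 ± 0.13) were among the others. Interferon response genes had 5 falls and 1 rise among 18 (7 and 1 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.250 with an estimated correlation). The largest were IFI44L (−1.29 ± 0.21) and GBP2 (−0.98 ± 0.15), and GBP1 gave −0.46 ± 0.12. This call ended with the dimmest 40% of genes left out (adjusted p = 0.163).

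Among 11 endothelial, pericyte and epithelial markers 2 rose against NTC and none fell, also adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.249 with an estimated correlation; adjusted p = 0.0614 without NTC replicate 6). Both, PDGFRB (0.87 ± 0.12) and NOTCH3 (0.75 ± 0.13), encode receptors of mural cells that tumour cells can also express. Of 8 macrophage, microglia and lymphocyte markers 0 passed in limma, also adjusted over the list alone and at an unadjusted p under 0.05 (camera, adjusted p = 0.577). Of 14 astrocyte markers 5 fell and none rose (6 and 2 adjusted over the list alone; adjusted p = 0.0795), including the fatty acid binding protein gene FABP7 (−1.86 ± 0.25) and the clusterin gene CLU (−1.54 ± 0.27). Matrix and mesenchymal genes had 8 rises and 4 falls among 33 (9 and 4 adjusted over the list alone; adjusted p = 0.0468, and adjusted p = 0.332 with an estimated correlation), with DCN (1.63 ± 0.21) and the basement membrane collagen gene COL4A1 (0.98 ± 0.10) up and the chitinase-like gene CHI3L1 (−2.60 ± 0.26) down. This call was also lost with quantile normalization (adjusted p = 0.0885), without replicate 6 (adjusted p = 0.112) and with IL4I1-KO 1, 3 or 4, NTC 5 or 6 or NTC.01 2, 3 or 6 left out (adjusted p up to 0.108).

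All 9 lists that camera called against NTC also passed by fry, with adjusted p from 0.000152 for transporters, ATF4 and inflammatory genes to 0.0229 for the cell cycle, and 8 passed by score; the matrix score did not (exact permutation p = 0.0844, adjusted 0.121). These tests called further lists that camera did not, 14 in all by fry and 15 by score. Among them were TGF-beta and YAP targets (fry adjusted p = 0.00398; score 0.0199 adjusted) and heat shock genes (0.00395; 0.0187), which were higher, and astrocyte (0.0186; 0.0199) and neuronal markers (0.0186; 0.0356), which were lower. Antigen presentation genes passed by score alone (0.0332 adjusted; fry adjusted p = 0.0685). Housekeeping genes also passed both (0.0186; 0.0345), with a score difference of −0.08. Without the member that changed most, the scores of TGF-beta and YAP targets (ACTA2 left out; exact permutation p adjusted to 0.457), astrocyte (FABP7; 0.126) and neuronal markers (SOX11; 0.787), antigen presentation (TAP1; 0.0634) and housekeeping genes (HPRT1; 0.124) did not pass, and the matrix score did (CHI3L1; 0.0166).

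The 2 control lines differed from each other as well. NTC.01 had more transcripts than NTC of the copper oxidase gene HEPH (2.94 ± 0.19), CHSY3 (2.74 ± 0.12), the glutamate receptor gene GRIK2 (2.34 ± 0.12) and NDNF (2.10 ± 0.25), and ATRNL1, HOXB9, DGKB, SESN3, ST6GAL2 and VIPR1 followed with values from 1.98 to 1.86. NDST4 was far lower in the clone (3.44 ± 0.36, SD, n = 6), where it was the lowest of all probe sets on 5 of 6 arrays and no exact fold is given. Also lower were SLC7A14 (−3.14 ± 0.31), IL13RA2 (−3.07 ± 0.32) and the chromatin protein gene HMGA2 (−2.34 ± 0.15). ANGPT2, CACNG7, CHI3L1, SRGN, SHC3 and FABP7 fell as well, with values from −2.21 to −2.07, and the dimmer group averaged under 7.73 in 18 of the 20 genes. Of 12655 genes 1007 passed the threshold, 289 higher and 718 lower in NTC.01, with 51 and 84 changed at least 2-fold, and over all genes groups did not overlap for 590, where chance gives 27.4. Of the 718 lower genes 202 were X-linked, and without the X-linked genes 714 genes passed. With the replicate number as a block 2081 genes passed, 612 higher and 1469 lower, including 1006 of the 1007.

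Gene lists separated the control clone from NTC too, in a comparison that shares its 6 NTC arrays with that of IL4I1-KO against NTC. ATF4 targets had 10 rises and no fall among 24 (11 adjusted over the list alone; adjusted p = 5.85e-08, and adjusted p = 0.180 with an estimated correlation), with STC2 (0.72 ± 0.14) among them. The 10 became 4 without NTC 4 or NTC.01 1, 5 without NTC 2 or NTC.01 2 and 6 without NTC 5 or NTC.01 5. Amino acid transporters had 3 rises and no fall among 15 (4 adjusted over the list alone; adjusted p = 0.000489, and adjusted p = 0.0224 with an estimated correlation), namely SLC7A11 (0.78 ± 0.17), SLC38A1 (0.74 ± 0.15) and SLC1A5 (0.64 ± 0.13). Inflammatory genes had 3 falls and no rise among 15, also adjusted over the list alone (adjusted p = 0.00337; adjusted p = 0.131 with an estimated correlation), including CCL2 (−1.32 ± 0.33) and the macrophage growth factor gene CSF1 (−0.72 ± 0.11). TGF-beta and YAP targets had 3 rises and no fall among 18 (6 adjusted over the list alone; adjusted p = 0.00198, and adjusted p = 0.0224 with an estimated correlation), with the actin gene ACTA2 (1.17 ± 0.15) and TAGLN (0.51 ± 0.11); 5 rose without IL4I1-KO 6 and 6 without NTC.01 3. Against NTC, IL4I1-KO had 4 rises and 2 falls in this list (5 and 3 adjusted over the list alone; adjusted p = 0.175), with ACTA2 at 1.54 ± 0.15 and CCN2 at 0.86 ± 0.15. Of the cell cycle list 0 of 32 passed between the controls in limma, also adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (camera, adjusted p = 0.677). Its score was higher in NTC.01 in 3 of 6 pairs, and with the replicate number as a block 2 members fell. That block brought the immediate early list from an adjusted p of 0.0854, with 1 fall (ETV4, −1.41 ± 0.24) among 20, to 0.0336, with 7 falls and 1 rise (with an estimated correlation, adjusted p = 0.619 without the block and adjusted p = 0.279 with it). It also raised the TGF-beta and YAP rises to 9, the transporter rises to 5 with 1 fall and the inflammatory falls to 5. By fry the transporter, TGF-beta and YAP (adjusted p = 0.000341 each), inflammatory (0.000532), ATF4 and neuronal lists (0.0116 each) passed, and by score the transporter (0.0332 adjusted), inflammatory and TGF-beta and YAP lists (0.0249 each), with ATF4 at 0.0597. In 7 lists, these 4 among them, all 6 pairs moved 1 way (paired exact permutation p = 0.0313, the smallest that 6 pairs can give), and none passed after adjustment over the lists (0.103).

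Genes that changed the same way against both controls numbered 717, with 282 higher and 435 lower in IL4I1-KO. The rises were led by PCDHB5 (3.44 against NTC.01 and 3.44 against NTC), SCRG1 (3.34 against NTC.01, with NTC near the lowest level of its arrays), CCL11 (4.32 and 2.06), CSMD1 (3.27 and 1.72), DCN (1.52 and 1.63) and the G protein gene GNAL (1.47 and 1.50), followed by SLC24A3, CCDC85A, the alkaline phosphatase gene ALPL and MAGEC1. The falls were led by SFRP2 (−4.29 and −2.82), VSNL1 (−2.98 and −2.56), the arginine deiminase gene PADI2 (−2.55 and −2.72), ITGA2 (−2.51 and −3.80), SLC14A1 (−2.24 and −3.11) and LYPD1 (−2.06 and −3.18), followed by ADGRE1, TSPAN13, the Wnt ligand gene WNT7B and TMPRSS15. In 311 of the 717 genes the 6 IL4I1-KO values lay outside the range of all 12 control arrays. A further 33 genes passed both comparisons in opposite directions. Independent lists of these sizes would share 40.3 higher and 49.9 lower genes, and in 100 simulations without effect the shared count had a median of 0 and a maximum of 2. The simulations hold no differences between lines, so they give no background for a clone against 2 control lines. Of the 717 genes, 102 also differed between the controls. With the IL4I1-KO arrays split, replicates 1 to 3 against NTC and 4 to 6 against NTC.01, 227 genes changed the same way, 79 higher and 148 lower.

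**Figure D2:**
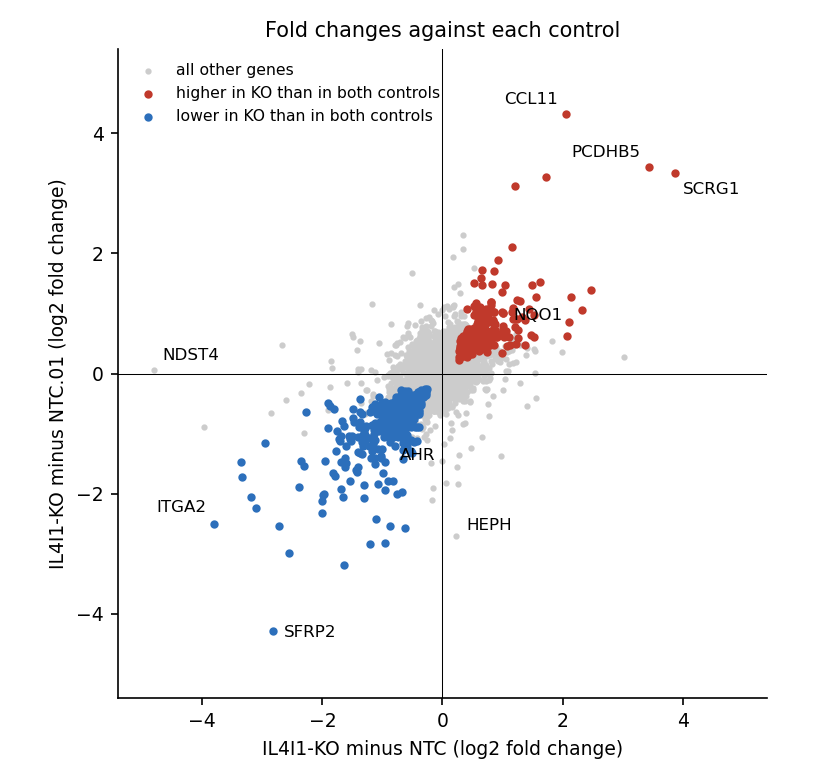
Each point is 1 of 12655 genes, placed by its log2 fold change in IL4I1-KO against NTC (horizontal axis) and against NTC.01 (vertical axis); red marks the 282 genes higher and blue the 435 genes lower in IL4I1-KO than in both controls. HEPH lies near 0 on the horizontal axis and far below 0 on the vertical one, and differs between the controls (2.94 in NTC.01 against NTC); NDST4 is at or near the lowest level of the arrays in both clones, so the size of its fold is not known.

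Across the 12655 genes, which are not independent replicates, the fold changes of the 2 knockout comparisons had a Pearson r of 0.63 and a Spearman rho of 0.550. Since both use the same IL4I1-KO arrays, r without any effect had a median of 0.526 in the simulations, with a range from −0.0930 to 0.888. The covariance was 0.0672 against a simulated 0.0110, a difference of 0.0562. With the IL4I1-KO arrays split, r was 0.405 and the covariance 0.0504.

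AHR itself was lower in IL4I1-KO (−1.13 ± 0.17 against NTC.01 and −0.88 ± 0.17 against NTC), with 0.26 ± 0.17 between the controls (adjusted p = 0.467). In NTC its value on replicate 6 was 8.99, where replicates 1 to 5 lay between 8.10 and 8.17. The AHR repressor gene AHRR fell against both (−0.82 ± 0.16 and −0.73 ± 0.16), as did TIPARP, an AHR-induced ADP-ribosyltransferase gene (−0.66 ± 0.13 and −0.49 ± 0.13). CYP1B1, a cytochrome P450 gene induced by AHR, gave 0.13 ± 0.13 and 0.17 ± 0.13 and did not pass (adjusted p = 0.613 and 0.480). ARNT, the dimerisation partner of AHR, gave −0.06 ± 0.08 and 0.03 ± 0.08 (adjusted p = 0.751 and 0.871). NQO1 rose (0.79 ± 0.10 and 1.01 ± 0.10) and ITGA2 fell (−2.51 ± 0.23 and −3.80 ± 0.23). As a list, the 18 measured AHR targets did not pass camera in any comparison. Camera asks whether a list moves 1 way relative to other genes, so rises and falls among its members can offset each other. Against NTC.01 2 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.620), against NTC 4 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.998), and between the controls 1 rose (STC2) and 2 fell (ITGA2 and HES1), also adjusted over the list alone (adjusted p = 0.583). Over all genes 12.6% passed against NTC.01, 11.7% against NTC and 7.96% between the controls, smaller shares than among the 18 targets. Whether the list holds more changed genes than other lists of its size was not tested. With the replicate number as a block 4 rose and 4 fell against NTC.01. The fixed lists share members. Each of the 4 rises against NTC was also in another list: NQO1 (NRF2), STC2 (ATF4), SLC7A5 (amino acid transporters) and VEGFA (hypoxia and glycolysis).

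The median, the mean and the test of the AHR list differed in sign. Against NTC.01 the median was 0.02, the mean −0.14 and camera's direction down; against NTC the median was −0.04, the mean −0.16 and camera's direction up; between the controls the median was 0.06, the mean −0.02 and camera's direction up. The list score of IL4I1-KO differed from that of NTC by −0.16, with an exact permutation p of 0.0238 (0.0365 after adjustment over the 23 lists). Against NTC.01 it differed by −0.14 and was lower in 6 of 6 same-numbered pairs. The unpaired exact permutation p was 0.0844 there (0.221 adjusted) and the paired one 0.0313, the smallest that 6 pairs can give (0.0799 adjusted). These score differences rested on ITGA2. Without it the difference was 0.050 against NTC (exact permutation p = 0.502, adjusted 0.642) and −0.0054 against NTC.01 (exact permutation p = 0.955, also adjusted), where 4 of 6 pairs were lower (paired exact permutation p = 0.969). By fry the list passed in no comparison (adjusted p = 0.578, 0.582 and 0.90).

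**Figure D3:**
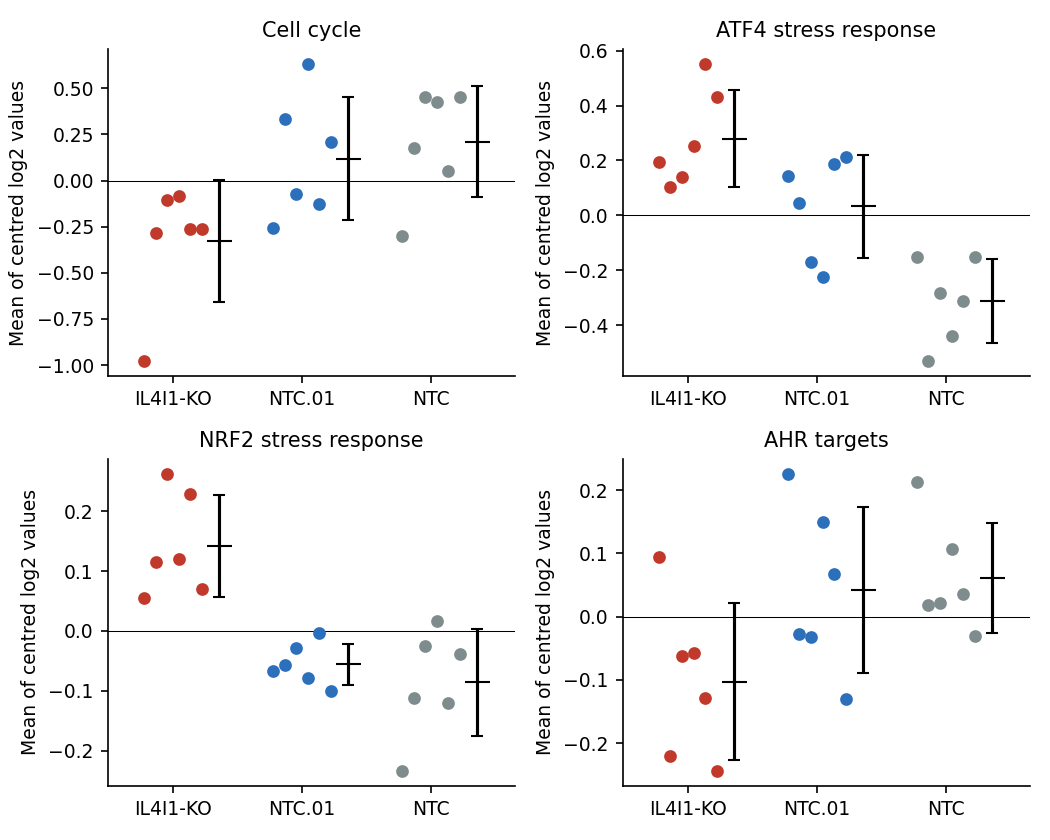
Scores of 4 gene lists on each of the 18 arrays, as the mean over the list's members of the log2 value minus that gene's mean over all arrays, with each group's mean and SD (n = 6) as a bar beside its points. NRF2 scores of all 6 IL4I1-KO arrays lie above those of all 12 control arrays (exact permutation p = 0.00216 against each control), ATF4 scores fall in the order IL4I1-KO (0.28), NTC.01 (0.03), NTC (−0.31), and cell cycle scores include 1 IL4I1-KO array at −0.98, far below the others.

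Among 15 measured genes of tryptophan, phenylalanine and tyrosine catabolism 2 fell and 1 rose against NTC.01, also adjusted over the list alone (adjusted p = 0.950), and 5 fell and 3 rose against NTC, also adjusted over the list alone (adjusted p = 0.577). The 5 falls became 3 without IL4I1-KO 6 or NTC 3 or 5. The kynureninase gene KYNU fell against both (−1.07 ± 0.17 and −0.87 ± 0.17), and the aldehyde dehydrogenase gene ALDH2 rose (1.06 ± 0.10 and 0.79 ± 0.10). AFMID, which encodes kynurenine formamidase, fell against NTC.01 (−0.76 ± 0.14). The tryptophan dioxygenase gene TDO2 was lower in IL4I1-KO than in NTC (−0.81 ± 0.12) and also lower in NTC.01 than in NTC (−0.76 ± 0.12). Between the controls the list had 2 falls, TDO2 and ACAT1 (−0.57 ± 0.13), and 1 rise, the tryptophanyl-tRNA synthetase gene WARS1 at 0.61 ± 0.12 (5 and 2 adjusted over the list alone; adjusted p = 0.615). With the replicate number as a block 5 fell and 2 rose between the controls, and 2 fell and 2 rose against NTC.01. Wnt and Notch targets moved both ways, with 3 rises and 3 falls among 17 against NTC.01 and 3 and 4 against NTC (3 and 4 against each control adjusted over the list alone; adjusted p = 0.673 and 0.998). The 4 falls against NTC became 2 without NTC 1, 2 or 3. Between the controls 1 fell (HES1) and none rose, also adjusted over the list alone (adjusted p = 0.635), and 4 fell with the replicate number as a block. The Wnt feedback gene NKD1 (−1.41 ± 0.24 and −1.19 ± 0.24) and TCF7 (−0.63 ± 0.14 and −0.74 ± 0.14) fell against both controls, while NOTCH3 (1.06 ± 0.13 and 0.75 ± 0.13) and its ligand gene JAG1 (0.66 ± 0.13 and 0.87 ± 0.13) rose.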

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

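Of the tests in this part, those of the small nucleolar RNA genes between the groups and under other scalings were chosen only after the result was seen, as were these genes themselves.

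For each named gene, the probe set of IL4I1 and NUP62 and each list score, the distance of the most extreme of a group's 6 arrays from its nearest neighbour was divided by the range of the 6. This ratio passed Dixon's critical value in 25 of 468 sets, where chance gives about 1 in 20, or 23.4. Of the 25 sets, 13 had an array of replicate 6 as the extreme one, and chance alone would spread such sets over the replicates. In NTC, replicate 6 was highest for AHR (ratio 0.927) and lowest for TSPAN7 (0.747), the hypoxia and glycolysis score (0.647) and the astrocyte score (0.711). In NTC.01, replicate 6 was highest for MKX (0.633) and lowest for NKD1 (0.766), TSPAN7 (0.762), the hypoxia and glycolysis score (0.710) and the astrocyte score (0.683). In IL4I1-KO, replicate 6 was highest for MKX (0.696) and lowest for HEPH (0.757), PDGFRB (0.776) and PHLDA1 (0.656). The other 12 sets were scattered. IL4I1-KO replicate 1 was lowest for the cell cycle score (0.774) and for its member TOP2A (0.661). IL4I1-KO replicate 3 was highest for COL3A1 (0.738) and replicate 5 for ST6GAL1 (0.670). In NTC, replicate 2 was lowest for ST6GAL1 (0.725), replicate 3 for TIMP3 (0.661) and replicate 4 for ACTA2 (0.638) and VLDLR (0.675), while replicate 4 was highest for NDNF (0.652). In NTC.01, the extreme was a high value each time: replicate 3 for SLC1A3 (0.780), replicate 4 for FOSL1 (0.753) and replicate 5 for the oligodendrocyte score (0.756).

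The 3 arrays of replicate 6 stood apart from replicates 1 to 5 in every group: their deviations from the group means correlated with each other at r = 0.635 to 0.677 across genes, against 0.0307 to 0.521 for the other same-numbered arrays. Small nucleolar RNA genes, short RNAs that guide the modification of ribosomal RNA, were far lower on these arrays (median shift of 55 genes −1.71 in IL4I1-KO, −1.40 in NTC and −1.70 in NTC.01, and −1.37 or lower after quantile normalization or median centring), while the other 12600 genes shifted by −0.04 to −0.01. The small nucleolar RNA genes themselves do not carry the whole pattern, since without these genes the lowest correlation between replicate 6 arrays was 0.611 and the highest among the others 0.511. Leaving out 55 genes cannot test a cause that lowered these RNAs and shifted other genes too, which stays open. A different growth state of the cells in that experiment may contribute and stays open, as the cell cycle list shifted by 0.0754 in IL4I1-KO, 0.282 in NTC and 0.10 in NTC.01, neither clearly moved nor near 0 in all 3 groups. No biological explanation from the design was tested, because each group holds 1 such array. Between groups 0 of the 55 genes passed in limma. At an unadjusted p under 0.05 in limma, 1 was higher and 2 lower in IL4I1-KO than in NTC, and 0 in the other comparisons. With the replicate number as a block 7 rose and 3 fell against NTC.01, 2 rose and 5 fell against NTC, and 6 fell between the controls.

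Probe sets left out of the gene tests differed between IL4I1-KO and both controls about as often as the tested genes, of which 5.67% changed the same way. Of 716 probe sets with several gene symbols 15 were higher and 21 lower, and of 1115 with no symbol 32 were higher and 19 lower.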

How the results depend on the processing

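Leaving out the arrays of replicate 6, the small nucleolar RNA genes or the X-linked genes, and for gene lists median centring, each array left out in turn and, beyond the AHR list, fry, the counts of list members with each array left out, and list scores without the member that changed most were tests chosen only after the result was seen. Of the results that passed their test, the AHR score against NTC alone turned its direction under an alternative run (−0.16, and 0.050 without ITGA2, exact permutation p adjusted from 0.0365 to 0.642). Leaving out the member that changed most ended 7 other score calls and added 1. The probe set of IL4I1 and NUP62 was lower in IL4I1-KO by −1.11 to −0.96 against NTC.01 and −0.98 to −0.86 against NTC. By camera or fry the AHR list passed under none of its 31 alternatives per comparison (adjusted p 0.509 to 0.866 against NTC.01, 0.163 to 1.00 against NTC and 0.231 to 0.900 between the controls), while its median lay on either side of 0 against each control. The correlation of the knockout comparisons ranged from 0.405 to 0.644. The authors' table holds no probe sets dim on nearly all arrays, but for most of the largest changes the dimmer group averaged under 7.73. How signal over background limits the calls can be judged only from these values and from the filter below.

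The counts of changed genes are given in the order IL4I1-KO against NTC.01, IL4I1-KO against NTC, NTC.01 against NTC, and the same way against both controls. They stayed within 1.5 times under 6 of the alternatives fixed in advance (2 groups at a time, trend and robust moderation, quantile normalization, median centring, mean of probe sets, all probe sets) and the 3 added ones: 1239 to 2261, 1387 to 1885, 714 to 1300 and 620 to 963. With each array left out they were 1272 to 1920, 1148 to 1770, 766 to 1145 and 576 to 839. They moved to 2560, 2638, 1557 and 1267 with array weights, to 3191, 2916, 2081 and 1549 with the replicate number as a block, and to 3126, 2883, 2068 and 1517 with it as a random block; the cause was not tested. The dim filter, which tests fewer genes, gave 991, 862, 529 and 434. Median centring gave 811 higher and 754 lower genes in IL4I1-KO against NTC.01, where 924 and 676 are reported. By construction fewer passed with a 2-fold threshold (182, 222, 135 and 88) or an adjusted p under 0.01 (807, 790, 554 and 349). The count against both controls was 227 with the IL4I1-KO arrays split, which leaves fewer arrays per comparison, and 1742 for IL4I1-KO against the mean of the controls, which asks for less. Chance assignment of arrays to groups is argued against for each count. Of 100 splits of the arrays only 1, the real one, gave as many, and the highest others were 474, 373, 44 and 0. These splits do not test differences that arise between clones, and the 2 controls, which differ without a knockout, passed the same test. With the block, 1 of 32 splits parting all 6 pairs, again the real one, gave as many for IL4I1-KO against NTC.01 (highest other 9) and for NTC.01 against NTC (highest other 0). IL4I1-KO and NTC do not count as paired, and 3 of their 6 numbers matched best.

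For the gene lists the values are medians, with the range of adjusted p over a list's alternatives. With an estimated correlation calls ended against NTC.01 for ATF4 (0.25; 0.00792 to 0.733), NRF2 (0.13; 0.00987 to 0.705), the cell cycle (−0.50; 1.26e-10 to 0.705) and immediate early genes (−0.18; 0.0167 to 0.705). Against NTC they ended for amino acid transporters (0.38; 0.000152 to 0.0913), ATF4 (0.69; 4.80e-13 to 0.0913), NRF2 (0.064; 0.00260 to 0.275), interferon (−0.30; 0.00325 to 0.250), inflammatory genes (−0.36; 0.000152 to 0.0913), the cell cycle (−0.53; 3.07e-12 to 0.332), the matrix list (0.081; 0.00516 to 0.332), immediate early genes (−0.37; 7.45e-06 to 0.190) and endothelial markers (0.28; 0.00398 to 0.249). Between the controls they ended for ATF4 (0.39; 6.24e-10 to 0.180) and inflammatory genes (−0.24; 0.000532 to 0.131). This setting allows for members that vary together, and fry, which does not compare a list with other genes, asks another question. With fry, calls ended against NTC.01 for ATF4 (0.25), the cell cycle (−0.50) and immediate early genes (−0.18), and lists passed that camera did not call: neuronal (−0.069) and heat shock (0.15; 0.0250 to 0.705) against NTC.01, TGF-beta and YAP (0.087; 0.00398 to 0.303), astrocyte (−0.10; 0.0186 to 0.356), neuronal (−0.054; 0.0186 to 0.589), heat shock (0.17; 0.00395 to 0.249) and housekeeping (−0.078; 0.0186 to 0.399) against NTC, and neuronal (0.099) between the controls. The cause was not tested for the changes that follow. Without replicate 6, calls ended against NTC.01 for ATF4 (0.29), NRF2 (0.15) and immediate early genes (−0.19) and against NTC for the matrix list (0.097), whose call also ended with quantile normalization (0.060) and with the block (0.081). The interferon call against NTC ended with the dim filter (−0.29). Antigen presentation against NTC (0.0211 to 0.495) passed without replicate 6 (−0.15), with quantile normalization (−0.19), the dim filter (−0.28), the block (−0.19) and median centring (−0.18), and hypoxia against NTC (0.0232 to 0.495) with the dim filter (0.081). The neuronal list passed against NTC.01 with quantile normalization (−0.084; 0.000276 to 0.377). Between the controls, immediate early genes passed with quantile normalization (−0.24) and the block (−0.26; 0.0336 to 0.619), and with the dim filter the matrix (0.042; 0.0293 to 0.619), neuronal (0.15; 0.0116 to 0.181) and endothelial lists (0.26; 0.00914 to 0.615) passed. With each array left out, some calls ended: medians were 0.18 to 0.30 for ATF4, 0.084 to 0.20 for NRF2 and −0.22 to −0.13 for immediate early genes against NTC.01, and 0.045 to 0.096 for the matrix list and 0.22 to 0.31 for endothelial markers against NTC. The NRF2 median moved by over 1.5 times against NTC without IL4I1-KO 5 (0.099) or NTC 4 (0.115) or 5 (0.11), with a range of 0.0517 to 0.115 and its call kept, and against NTC.01 without IL4I1-KO 5 (0.084) or 6 (0.20); the matrix median against NTC did so without NTC 5 (0.045). The block changed no other call of a list. Of the named genes' calls it left 264 as they were and added 8. Quantile normalization left 271 and ended 1. With arrays left out in turn, 34 of 240 such calls ended without at least 1 array, and 5 of 32 named genes that did not pass did so without at least 1.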

Other observations

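Of the tests in this part, the comparison of NUP62 with all genes, which replaced an earlier test of the same idea and whose limits were set anew, the medians of whole chromosomes other than the X, the exact tests of list scores, fry, the counts of list members with each array left out, and the tests of the X-linked genes for a few strong genes and for a shift in each of 4 consecutive parts were chosen only after the result was seen.

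Several fixed lists outside the main comparisons held single changed genes and did not pass camera. Of 26 hypoxia and glycolysis genes 4 rose and 1 fell in IL4I1-KO against NTC.01 (5 and 1 adjusted over the list alone; adjusted p = 0.234; 7 rises with the replicate number as a block) and likewise 4 and 1 against NTC, also adjusted over the list alone (adjusted p = 0.0795). They included the MYC antagonist gene MXI1 (0.59 ± 0.13 and 0.66 ± 0.13), the angiogenic factor gene VEGFA (0.40 ± 0.11 and 0.43 ± 0.11) and, against NTC, the mitophagy receptor gene BNIP3L (0.41 ± 0.08). The hypoxia score was higher than in NTC.01 in 6 of 6 pairs (exact permutation p = 0.227, adjusted 0.436). The glycolytic gene PGK1 rose against NTC.01 (0.39 ± 0.10) and was the 1 fall between the controls (−0.45 ± 0.10), also adjusted over the list alone (adjusted p = 0.764). PGK1 is X-linked, and X-linked genes as a whole had medians of 0.26 and −0.45 in these comparisons. It was also the 1 call of the housekeeping list in each of them. Other named genes can be X-linked too, and their linkage is not given here. A call of such a gene can belong to this shift of the X-linked genes. Among 17 heat shock and unfolded protein response genes 5 rose and 2 fell against NTC (6 and 2 adjusted over the list alone; adjusted p = 0.0776). The endoplasmic reticulum stress factor gene XBP1 (0.47 ± 0.11) and the chaperone gene HYOU1 (0.44 ± 0.11) rose, and the cytosolic co-chaperone genes DNAJB1 (−0.58 ± 0.14) and BAG3 (−0.57 ± 0.11) fell. The score of this list was higher in IL4I1-KO than in NTC (exact permutation p = 0.00649, and 0.0187 after adjustment over the 23 lists; fry, adjusted p = 0.00395). It was also higher than in NTC.01 in 6 of 6 pairs, where fry passed (adjusted p = 0.0250) and the score missed the threshold after adjustment (exact permutation p = 0.0130, adjusted 0.0747). Against NTC.01 1 rose and 2 fell in this list (2 and 2 adjusted over the list alone; adjusted p = 0.365; 4 rises with the block), and between the controls 0 passed, also adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 in limma (adjusted p = 0.583; 2 rises and 1 fall with the block). Of 22 p53 targets 2 rose and 3 fell against NTC.01 (2 and 4 adjusted over the list alone; adjusted p = 0.60; 5 and 5 with the block) and against NTC, also adjusted over the list alone (adjusted p = 0.577). The receptor gene EDA2R fell against both controls (−0.96 ± 0.14 and −0.63 ± 0.14), the cell cycle inhibitor gene CDKN1A against NTC.01 (−0.47 ± 0.10) and the pro-apoptotic gene BAX against NTC (−0.46 ± 0.12), where the stress sensor gene SESN2 rose (0.55 ± 0.12). Between the controls 1 p53 target rose, and 0 did adjusted over the list alone (adjusted p = 0.833; 3 with the block).

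Of 15 antigen presentation genes 1 rose and 3 fell against NTC (1 and 5 adjusted over the list alone; adjusted p = 0.0534), among them B2M, the light chain of class I molecules (−0.29 ± 0.07). The 3 falls became 1 without IL4I1-KO 1 or 6 or NTC 1, 2 or 5, and 5 without NTC.01 6. Against NTC.01 0 passed in limma, also adjusted over the list alone, with 2 lower at an unadjusted p under 0.05 (adjusted p = 0.365; 2 falls with the block), and between the controls 1 rose, HLA-DPB1 (0.53 ± 0.12), also adjusted over the list alone (adjusted p = 0.525; 2 falls with the block). Inflammatory genes had 2 rises and 1 fall among 15 against NTC.01 (2 and 2 adjusted over the list alone; adjusted p = 0.581; 4 and 4 with the block). The rises were the adhesion molecule genes ICAM1 (0.75 ± 0.16) and VCAM1 (0.68 ± 0.13, and 0.70 ± 0.13 against NTC). The viral RNA sensor gene RIGI (−0.93 ± 0.17) and the antiviral GTPase gene MX1 (−0.70 ± 0.12) were the 2 of 18 interferon response genes that fell between the controls, and none rose (2 and 1 adjusted over the list alone; adjusted p = 0.467; 4 and 1 with the block). Of 33 matrix genes 5 rose and 4 fell between the controls (6 and 4 adjusted over the list alone; adjusted p = 0.130), with the metalloproteinase inhibitor gene TIMP3 up (0.97 ± 0.12). Astrocyte markers had 3 falls among 14 against NTC.01 (3 and 1 rise adjusted over the list alone; adjusted p = 0.60; 3 falls and 2 rises with the block), including the tetraspanin gene CD9 (−0.58 ± 0.12, and −0.59 ± 0.12 against NTC), and 1 fall between the controls (3 adjusted over the list alone; adjusted p = 0.407; 4 with the block). The tight junction gene CLDN11 was the 1 of 9 oligodendrocyte markers that fell against NTC (−0.78 ± 0.19), also adjusted over the list alone (adjusted p = 0.577). Of 19 cholesterol synthesis genes the sterol isomerase gene EBP fell between the controls (−0.63 ± 0.15; 2 fell adjusted over the list alone; adjusted p = 0.254; 2 falls and 1 rise with the block).

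The remaining lists gave few calls. Against NTC.01, 0 of 19 cholesterol genes (1 higher and 2 lower at an unadjusted p under 0.05 in limma; adjusted p = 0.620; 2 rises and 1 fall with the block), 0 of 9 oligodendrocyte markers (0 unadjusted; adjusted p = 0.581) and 0 of 8 macrophage, microglia and lymphocyte markers (0 unadjusted; adjusted p = 0.60) passed. Against NTC 0 cholesterol genes passed (0 unadjusted; adjusted p = 0.577). Between the controls 0 oligodendrocyte markers (1 higher and 1 lower unadjusted; adjusted p = 0.764), 0 macrophage markers (2 higher unadjusted; adjusted p = 0.254) and 0 of 11 endothelial markers (2 higher and 1 lower unadjusted; adjusted p = 0.126; 2 rises and 1 fall with the block) passed. None of these 0 counts changed when adjusted over the list alone. Housekeeping genes had 1 rise among 12 against NTC.01 (adjusted p = 0.704; 1 rise and 1 fall with the block), 2 falls against NTC (adjusted p = 0.305) and 1 fall between the controls (adjusted p = 0.553; 2 with the block), also adjusted over the list alone. Against NTC.01, amino acid transporters had 2 falls among 15, also adjusted over the list alone (adjusted p = 0.950; 4 rises and 3 falls with the block). TGF-beta and YAP targets had 3 falls among 18 (4 and 1 rise adjusted over the list alone; adjusted p = 0.401; 6 and 4 with the block), and these 3 falls became 0 without NTC.01 2, 1 without IL4I1-KO 6 and 5 without NTC.01 6. Endothelial markers had 2 rises among 11, also adjusted over the list alone (adjusted p = 0.60). Neuronal markers had 2 falls among 14 against NTC (2 and 1 rise adjusted over the list alone; adjusted p = 0.577) and 2 rises between the controls, also adjusted over the list alone (adjusted p = 0.126; 3 and 1 fall with the block). The NRF2 list had 1 rise among 19 between the controls, also adjusted over the list alone (adjusted p = 0.615; 3 rises and 3 falls with the block), with a median of −0.05, a mean of 0.03 and camera's direction up. Over all lists and comparisons, 96 counts of rises or falls were 2 or fewer, counts of 0 included, and 44 of these moved by over 1.5 times with at least 1 array left out, by at most 3 genes.

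NUP62 fell with the probe set it shares with IL4I1 in IL4I1-KO against both controls. That NUP62 fell as any gene may between clones stays open, since 240 genes, or 1.90% of all, fell at least as far against both controls. Loss of a copy of the chromosome region in the clone cannot be told apart from an effect of the guide on the overlapping gene: the 20 nearest measured protein-coding neighbours had medians of −0.22 (SE of the mean 0.0418) against NTC.01 and −0.151 (SE 0.0358) against NTC, short of the −0.30 and −0.28 set for a lost copy but not clearly above the −0.15 and −0.14 set against it. Of these neighbours 18 and 16 were lower, 4 and 3 passed the threshold, and the 840 measured genes of the same chromosome had medians of −0.16 and −0.15. An effect of the edit itself on NUP62 stays open, as untested.

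X-linked genes were lower in NTC.01 than in NTC: the 397 measured had a median of −0.45 (−0.42 after quantile normalization or median centring) and made up 28.1% of the falls, and IL4I1-KO lay between, at 0.26 against NTC.01 and −0.17 against NTC. A technical trend along the chromosomes is argued against, since the shift relative to all genes was −0.42 and the largest of 30 splits of arrays within a line 0.0604, and so are a few strong genes, as 82.1% lay below 0. Copy number differences between the lines stay open: fold changes of genes 11 to 20 apart correlated at 0.0863 to 0.103 in the 3 comparisons, each above every shuffled gene order (up to 0.00964) and inside the range of splits within a line (up to 0.128), which had been set to argue against them, but this average over all chromosomes dilutes a shift of single ones, and 5 of 22 autosomes shifted by over 2 times their largest split in at least 1 comparison, such as chromosome 20 in IL4I1-KO against NTC.01 (0.175; split 0.0655) and chromosome 16 in NTC.01 against NTC (−0.151; split 0.0572). Chromosome 20 shifted by −0.138 in NTC.01 against NTC and by 0.0557 in IL4I1-KO against NTC, the latter inside its split. A shift of the whole X chromosome, by a lost copy or by silencing, may be present in the control clone and stays open: each of 4 consecutive parts of the X-linked genes in reference order shifted down relative to all genes, the least by −0.34, with 0.188 as its largest split within a line. Expression alone does not separate a lost copy from silencing, and clone and passage history were not tested.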
